A study of Homo sapiens with 60 samples.

How the data were processed

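The deposited table holds expected counts from RSEM for 60675 genes in 279 columns. The 60 columns of this series were used, and the 219 other columns were not used in any step. The submitters' notes name the MGIEasy RNA Directional kit, MGIseq sequencing of 100 bp paired-end reads, FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 on hg38. They do not state the annotation release or the strand setting of the counting. Of the values 90.8% were whole (tolerance 1e-9) and 10684 genes held values that were not, which were rounded. Genes were named by identifier from an annotation table, 57055 of them, and positions are on GRCh38. HMOX1 (ENSG00000100292) lies on chromosome 22 at 35380361 to 35394214, and ID3 (ENSG00000117318) on chromosome 1 at 23557918 to 23559794.

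Choices were made before the data were examined unless stated otherwise. The 57 libraries of the vehicle and of the 18 groups with 3 replicates were fitted together with edgeR (quasi-likelihood F test, TMM scaling, filterByExpr, 1 mean per group). Genes with a Benjamini-Hochberg adjusted p below 0.05 over the 17676 genes tested were called, with no minimum fold. The dose trend is the difference of the high and the low dose divided by 2, the log2 change per 5-fold step of dose. The common dispersion was 0.00656. A prior count of 2 entered the log2 CPM values of single libraries, and the fold changes used the default prior count of edgeR. SE is the log2 change divided by the square root of its F value. Libraries pooled in 1 fit share the spread of the 2 Astragali Radix libraries that stand apart, and fits without them, or of the compared groups by themselves, gave more calls in most comparisons.

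The 31 gene lists were tested with camera from limma (two-sided, preset correlation 0.01), adjusted over lists and comparisons within each of 3 families: against the vehicle, dose trends and between extracts. This made 899 tests over 29 comparisons, of which 356 were called, and 206 with an estimated correlation. The median given for a list is over its measured members. Counts adjusted over the list alone correct each gene for the members of its list.

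Genes named in the text follow a rule: the 8 largest rises and 8 largest falls of each high dose against the vehicle among called genes of at least 5 CPM whose 3 libraries lie on one side of the vehicle, up to 4 members of each called list with the smallest adjusted p, the 5 largest changes each way of each dose trend and of each comparison between extracts, and 21 genes fixed in advance. NEAT1, CCL2 and PTGS2 at the low doses were added after their values were seen. Clone-based names were left out. This gave 343 genes. Replicate numbers were tested for pairing by the correlation over genes of deviations from the group mean. These correlations were weak (median r 0.034 for the same number, -0.015 for other numbers), so no block enters the test. Still, 49 of 57 libraries lay closer to libraries of their own number, so a small effect of the number is present. A block by number is among the alternatives.

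In a self-test on Samul-tang high against the vehicle, 50 genes each were given changes of 1.25, 1.5, 2 and 4-fold, and 19, 40, 49 and 48 were recovered, while 7 of 17476 unchanged genes were called. Transcript length and GC content of 17552 genes served to remove trends per library with splines, an alternative added after the data were examined, as was the fit without Astragali Radix low replicates 1 and 2. With simulated length and GC biases in 2 libraries, 3510 unchanged genes were called without that correction and 9 with it. These biases were built from the same length and GC values that the correction fits. The self-test therefore does not show how well the correction works on the real libraries. The Rehmanniae Radix Preparata libraries, 1 per dose, were compared with the mean of the vehicle without a test, and each list's median was ranked among 10000 random lists of matched expression. The similarity of extracts is the Pearson correlation across genes of the dose-trend slopes.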

Results

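RNA was sequenced from SW1783 cells, an established human astrocytoma line, 24 h after the cells received herbal extracts prepared with ethanol or their DMSO vehicle. The samples fell into 3 vehicle libraries, 18 groups of 3 libraries (6 extracts at 3 doses) and 3 single libraries of Rehmanniae Radix Preparata, prepared Rehmannia root, 60 libraries in all. Astragali Radix (astragalus root) and Cinnamomi Cortex (cinnamon bark) are single herbs, and Sagunja-tang, Samul-tang, Palmul-tang and Sibjeondaebo-tang are traditional formulas of several herbs. By their recipes, Palmul-tang joins the herbs of Sagunja-tang and Samul-tang, and Sibjeondaebo-tang adds Astragali Radix and Cinnamomi Cortex to Palmul-tang. Astragali Radix was given at 220, 44 and 8.8 µg/mL and every other extract at 500, 100 and 20 µg/mL, called high, medium and low dose here. Total expected counts per library ranged from 19793426 to 37152413, and those of the vehicle libraries from 24212236 to 26167549. The labels of the vehicle libraries give 0.1% DMSO and the text of the series 2%, and which holds was not resolved. The comparisons ask which genes differed between each extract and the vehicle, which changed with its dose (no vehicle library enters this test), and how the formulas differed from each other at the high dose. The vehicle libraries carry a label code of unstated meaning that no extract library shares. Extract and code therefore cannot be told apart in any count of genes against the vehicle. Values are CPM (counts scaled to a common, normalised library total) and log2 ratios ± SE from edgeR with n = 3 libraries per group, over 17676 genes tested. The labels do not say whether the 3 replicates were separate cultures, so each p measures the spread between these libraries alone.

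At the high dose of Astragali Radix, antioxidant, heat shock and amino acid stress genes rose together while mitotic genes fell. HMOX1, which encodes a heme-degrading enzyme, rose 75.6-fold from 84.3 CPM in the vehicle to 6371 CPM (log2 6.24 ± 0.11, adjusted p = 2.28e-39). All 25 NRF2 antioxidant targets rose, also adjusted over the list alone (median log2 2.23, adjusted p of the list = 1.69e-41). Among them were SRXN1 and TXNRD1, which keep protein thiols reduced, at log2 3.49 ± 0.06 and 2.67 ± 0.07. Of 21 genes of the ATF4 amino acid response 20 rose (median log2 2.97, adjusted p = 1.8e-61), with the stress pseudokinase gene TRIB3 at 5.46 ± 0.08 and ASNS, asparagine synthetase, at 3.18 ± 0.05. All 15 heat shock genes rose (median log2 1.93, adjusted p = 1.92e-19), and so did HSPA6, an inducible chaperone gene outside that list, from 0.18 to 176 CPM (log2 9.91 ± 0.32). The lists of lysosome genes (20 of 20 rose, median log2 1.17, adjusted p = 2.43e-17) and of hypoxia and glycolysis genes (24 of 24, median 0.96, adjusted p = 1.06e-21) also rose. All 25 G2/M and mitosis genes fell (median log2 -1.90, adjusted p = 2.92e-34). The counts of these lists were the same adjusted over the list alone. The proliferation marker MKI67 went from 275 to 14.9 CPM (log2 -4.20 ± 0.16), while CDKN1A, an inhibitor of the cell cycle, rose by log2 5.52 ± 0.08. In all, 12052 of 17676 genes passed the test, 5763 higher and 6289 lower, 1935 and 2875 of them by at least 2-fold. With 68.2% of genes called, the split into higher and lower depends on where the TMM scaling sets no change. All 3 libraries lay on one side of all 3 vehicle libraries for each gene named here, which for the largest rises and falls was a condition of the choice.

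Smaller groups also changed at the high dose of Astragali Radix. ER unfolded protein genes rose in 14 of 17 (median log2 0.50, adjusted p = 1.83e-06), MAPK feedback and early genes in 15 of 20 with 3 lower (median 0.94, adjusted p = 1.5e-08) and cholesterol synthesis genes in 18 of 24 with 3 lower (median 0.56, adjusted p = 0.00446). The p53 targets rose in 9 of 18 with 3 lower (median log2 0.27, adjusted p = 2.85e-05), and glucocorticoid targets in 5 of 9 with 2 lower (median 0.59, adjusted p = 0.00432). These counts were the same adjusted over the list alone. All 32 cytosolic ribosomal protein genes rose (median log2 0.85, adjusted p = 2.15e-06), but this list had adjusted p = 0.427 with an estimated correlation. BMP and SMAD targets fell in 7 of 10 with 2 higher (median log2 -0.91, adjusted p = 0.0358; adjusted p = 0.201 with an estimated correlation), among them ID1, an inhibitor of differentiation, at log2 -3.13 ± 0.17, and ID3, of the same family, at -2.08 ± 0.11. The other lists named for this dose kept their calls with the estimated correlation. CYP1B1, which oxidises aromatic compounds and steroids, fell by log2 -3.77 ± 0.07.

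The medium dose of Astragali Radix again raised all 25 NRF2 targets (25 adjusted over the list alone, median log2 0.92, adjusted p = 4.1e-117), HMOX1 by log2 3.53 ± 0.10. Metallothionein and zinc genes, which bind metal ions, fell in 4 of 6 (5 adjusted over the list alone, median log2 -1.25, adjusted p = 1.81e-17), with MT2A at log2 -1.37 ± 0.11. BMP and SMAD targets fell in 9 of 10 with 1 higher (median log2 -0.55, adjusted p = 3.9e-07), and hypoxia and glycolysis genes rose in 14 of 24 (15 adjusted over the list alone, adjusted p = 2.23e-11). At the low dose 20 of 25 NRF2 targets rose and 1 fell, also adjusted over the list alone (median log2 0.49, adjusted p = 2.64e-11). HMOX1 rose there by log2 1.24 ± 0.09, and by 0.90 without low replicates 1 and 2, where the group is 1 library assumed to vary like the other groups. These 2 libraries stood apart. The SD over genes of their log2 deviation was 0.518 and 0.755, against 0.126 in replicate 3. Deviations were taken from the mean of the replicated libraries outside the high and low dose of this extract. Transcript length and GC content took 34.3% and 52.3% of their variance, and mitochondrial genes 5.93%, 1.38% and 4.97% of the counts of replicates 1, 2 and 3 against 7.55% to 8.04% in the vehicle. The list test at this dose called ribosomal protein genes (24 of 32 higher, median log2 0.39, adjusted p = 4.57e-10; adjusted p = 0.281 with an estimated correlation), nuclear oxidative phosphorylation genes (21 of 27 higher, 0.41; adjusted p = 0.138 with an estimated correlation) and mitochondrially encoded genes (13 of 13 lower, -1.08; adjusted p = 0.149 with an estimated correlation). Without replicates 1 and 2 the ribosomal list turned to lower with an adjusted p of 0.386.

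The medium dose of Astragali Radix changed 2927 genes and the low dose 7201, 3814 higher and 3387 lower. Without low replicates 1 and 2, where the group is a single library whose spread is taken from the other groups, the low-dose count was 2920, of which 1623 were shared with the full set and 1418 of these moved the same way. With dose, 12371 genes passed the test, 5535 higher and 6836 lower. Without the same libraries that count was 12034, with 10020 shared and 9826 in the same direction. A fit of the low-dose group and the vehicle by themselves called 0 of 15715 genes by edgeR, with 1782 at an unadjusted p below 0.05, while DESeq2 over all groups called 7139.

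Cinnamomi Cortex raised HMOX1 with dose, and its high dose lowered cholesterol synthesis genes. From the low to the high dose HMOX1 rose 5.3-fold, from 69.1 to 366 CPM (log2 1.203 ± 0.048 per 5-fold dose step, adjusted p = 9.44e-24). ANGPTL4, an inhibitor of lipoprotein lipase, rose 4.58-fold, PLIN2, a coat protein of lipid droplets, 2.29-fold, and CPT1A, which admits fatty acids to mitochondria, 1.64-fold. CYP1B1 fell with dose by log2 -0.30 ± 0.03 per step and the retinaldehyde reductase gene DHRS3 by -0.50 ± 0.06. Against the vehicle, 12 of 24 cholesterol synthesis genes fell at the high dose (13 adjusted over the list alone, median log2 -0.24, adjusted p = 3.53e-09), with the sterol sensor partner INSIG1 at log2 -0.91 ± 0.06. The NRF2 list rose with dose in 5 of 25 genes (11 adjusted over the list alone, adjusted p = 4.42e-37), and AhR targets, which respond to aromatic compounds, fell in 2 of 8 with 1 higher (1 higher and 4 lower adjusted over the list alone, adjusted p = 8.36e-06). These list calls held with an estimated correlation. The dose test called 78 genes, 43 higher and 35 lower. It called 43 without high replicate 1, 51 without low replicate 1, 50 without high replicate 2 and 47 without low replicate 3, and DESeq2 called 122. Against the vehicle 2872 genes differed at the high dose, 1360 higher and 1512 lower, and 1878 without vehicle replicate 1. The medium and low doses gave 2302 and 2341, although few genes changed with dose. Extract and label code cannot be told apart in these counts.

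Sagunja-tang raised antioxidant and amino acid response genes with dose and lowered YAP/TAZ targets. HMOX1 rose 3.28-fold from the low to the high dose (log2 0.86 ± 0.05 per step, adjusted p = 4.07e-18). GDF15, a stress-induced cytokine gene, rose 2.67-fold, THBD, thrombomodulin, 2.15-fold and FTL, the ferritin light chain, 2.02-fold. Of the NRF2 targets 21 of 25 rose (24 adjusted over the list alone, median log2 0.24 per step, adjusted p = 7.36e-94), of the ATF4 list 14 of 21 rose and 1 fell (16 and 1 adjusted over the list alone, adjusted p = 6.28e-30), and of the AhR targets 4 of 8 rose (4 higher and 1 lower adjusted over the list alone, adjusted p = 6.49e-11). YAP/TAZ targets, linked to cell shape and growth, fell with dose in 8 of 12 (9 adjusted over the list alone, median log2 -0.15, adjusted p = 1.56e-23). Among them, CCN2, a matricellular growth factor gene, fell by log2 -1.09 ± 0.08 at the high dose against the vehicle. Hypoxia and glycolysis genes fell in 9 of 24 with 1 higher (2 higher and 11 lower adjusted over the list alone, adjusted p = 1.64e-08). KRT18, a keratin, and the hyaluronan-degrading gene CEMIP were among the genes with the steepest falls (log2 -0.38 ± 0.05 and -0.40 ± 0.05 per step). All these calls held with an estimated correlation. With dose 668 genes changed, 365 higher and 303 lower, and 437, 402, 412, 427 and 422 without, in turn, high replicate 1, high replicate 2, low replicate 2, high replicate 3 and low replicate 3. Against the vehicle 4021 genes changed at the high dose, 1976 higher and 2045 lower.

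Samul-tang raised NRF2 and AhR targets with dose and lowered BMP and SMAD targets and cholesterol synthesis genes. ANGPTL4 rose 2.89-fold from the low to the high dose, HMOX1 2.82-fold (log2 0.75 ± 0.05 per step, adjusted p = 7.27e-16), the growth factor binding protein gene IGFBP1 2.69-fold and SLC7A11, a cystine transporter, 2.2-fold. NRF2 targets rose in 18 of 25 (23 adjusted over the list alone, median log2 0.20 per step, adjusted p = 5.86e-95) and AhR targets in 6 of 8 (7 adjusted over the list alone, median 0.28, adjusted p = 6.28e-34). At the high dose CYP1B1 was log2 0.62 ± 0.06 above the vehicle. BMP and SMAD targets fell with dose in 6 of 10 (9 adjusted over the list alone, median log2 -0.26, adjusted p = 6.57e-22), with ID3 at log2 -0.43 ± 0.05 per step. Cholesterol synthesis genes fell in 6 of 24 (13 adjusted over the list alone, adjusted p = 1.14e-17), fatty acid synthesis genes in 4 of 12 (4 adjusted over the list alone, adjusted p = 1.99e-13) and metallothionein and zinc genes in 2 of 6 (1 higher and 5 lower adjusted over the list alone, adjusted p = 1.63e-07). All these calls held with an estimated correlation. With dose 249 genes changed, 132 higher and 117 lower, and 164 without low replicate 1 and 157 without high replicate 2. Against the vehicle 3471 genes changed at the high dose, 1655 higher and 1816 lower, and 2294 without high replicate 2.

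Palmul-tang lowered BMP and SMAD targets and raised antioxidant and amino acid response genes with dose. Of the 10 BMP and SMAD targets 9 fell, also adjusted over the list alone (median log2 -0.51 per step, adjusted p = 4.27e-42). ID3 fell from 172 CPM in the vehicle to 53.3 CPM at the high dose (log2 -1.69 ± 0.10), ID2 by log2 -1.70 ± 0.12 and the transcription factor gene ATOH8 by -1.55 ± 0.14. HMOX1 rose 3.57-fold from the low to the high dose (log2 0.92 ± 0.05 per step, adjusted p = 2.59e-19), GDF15 3.37-fold, ANGPTL4 3.17-fold and ATP2A3, a calcium pump of the endoplasmic reticulum, 2.72-fold. NRF2 targets rose in 20 of 25 (25 adjusted over the list alone, median log2 0.28, adjusted p = 3.15e-105), ATF4 genes in 12 of 21 (17 adjusted over the list alone, adjusted p = 1.08e-37), lysosome genes in 6 of 20 (12 adjusted over the list alone, adjusted p = 1.98e-15) and AhR targets in 3 of 8 (5 adjusted over the list alone, adjusted p = 1.66e-12). G2/M and mitosis genes fell in 11 of 25 (24 adjusted over the list alone, median log2 -0.12, adjusted p = 9.07e-24) and YAP/TAZ targets in 4 of 12 (8 adjusted over the list alone, adjusted p = 1.59e-12). All these calls held with an estimated correlation. With dose 651 genes changed, 339 higher and 312 lower, and 401 without low replicate 1, 429 without high replicate 3 and 387 without low replicate 3. Against the vehicle 3584 genes changed at the high dose, 1774 higher and 1810 lower.

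Sibjeondaebo-tang raised all 25 NRF2 targets with dose, also adjusted over the list alone (median log2 0.45 per step, adjusted p = 7.82e-115). HMOX1 rose 8.54-fold from the low to the high dose, to 595 CPM (log2 1.55 ± 0.05 per step, adjusted p = 6.81e-28), the aldo-keto reductase gene AKR1C1 3.36-fold, FTH1, the ferritin heavy chain, 2.89-fold and the quinone reductase gene NQO1 2.8-fold. Reads of AKR1C1 can be shared with its close relatives in the aldo-keto reductase family. ANGPTL4 rose 5.06-fold. BMP and SMAD targets fell in 9 of 10 (10 adjusted over the list alone, median log2 -0.47, adjusted p = 5.59e-17), with ID3 at log2 -1.35 ± 0.10 against the vehicle at the high dose. ATF4 genes rose with dose in 17 of 21, also adjusted over the list alone (median log2 0.24, adjusted p = 6.88e-23), MAPK feedback and early genes in 10 of 20 (11 adjusted over the list alone, adjusted p = 1.57e-06) and NF-kB and inflammatory genes in 9 of 21 with 2 lower (11 and 3 adjusted over the list alone, adjusted p = 0.00169). ANKRD1, a YAP/TAZ target gene, fell by log2 -1.90 ± 0.11 against the vehicle. Ribosomal protein genes rose with dose in 17 of 32 (23 adjusted over the list alone, adjusted p = 0.24 with an estimated correlation) and nuclear oxidative phosphorylation genes in 21 of 27 (22 adjusted over the list alone, adjusted p = 0.105 with an estimated correlation). Length and GC took 8.3%, 5.6% and 15% of the variance of the 3 high-dose libraries, and 34.3% and 52.3% in the 2 libraries of Astragali Radix that stood apart. The deviations of the high-dose libraries had rank correlations with transcript length of -0.35, -0.264 and -0.465. Those of the low-dose libraries had 0.244, 0.243 and 0.304, so the dose trend of this extract runs partly along transcript length. The cause was not tested. With dose 3763 genes changed, 1870 higher and 1893 lower, and 2201 without high replicate 3. Against the vehicle 4084 genes changed at the high dose, 1982 higher and 2102 lower.

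**Figure D1:**
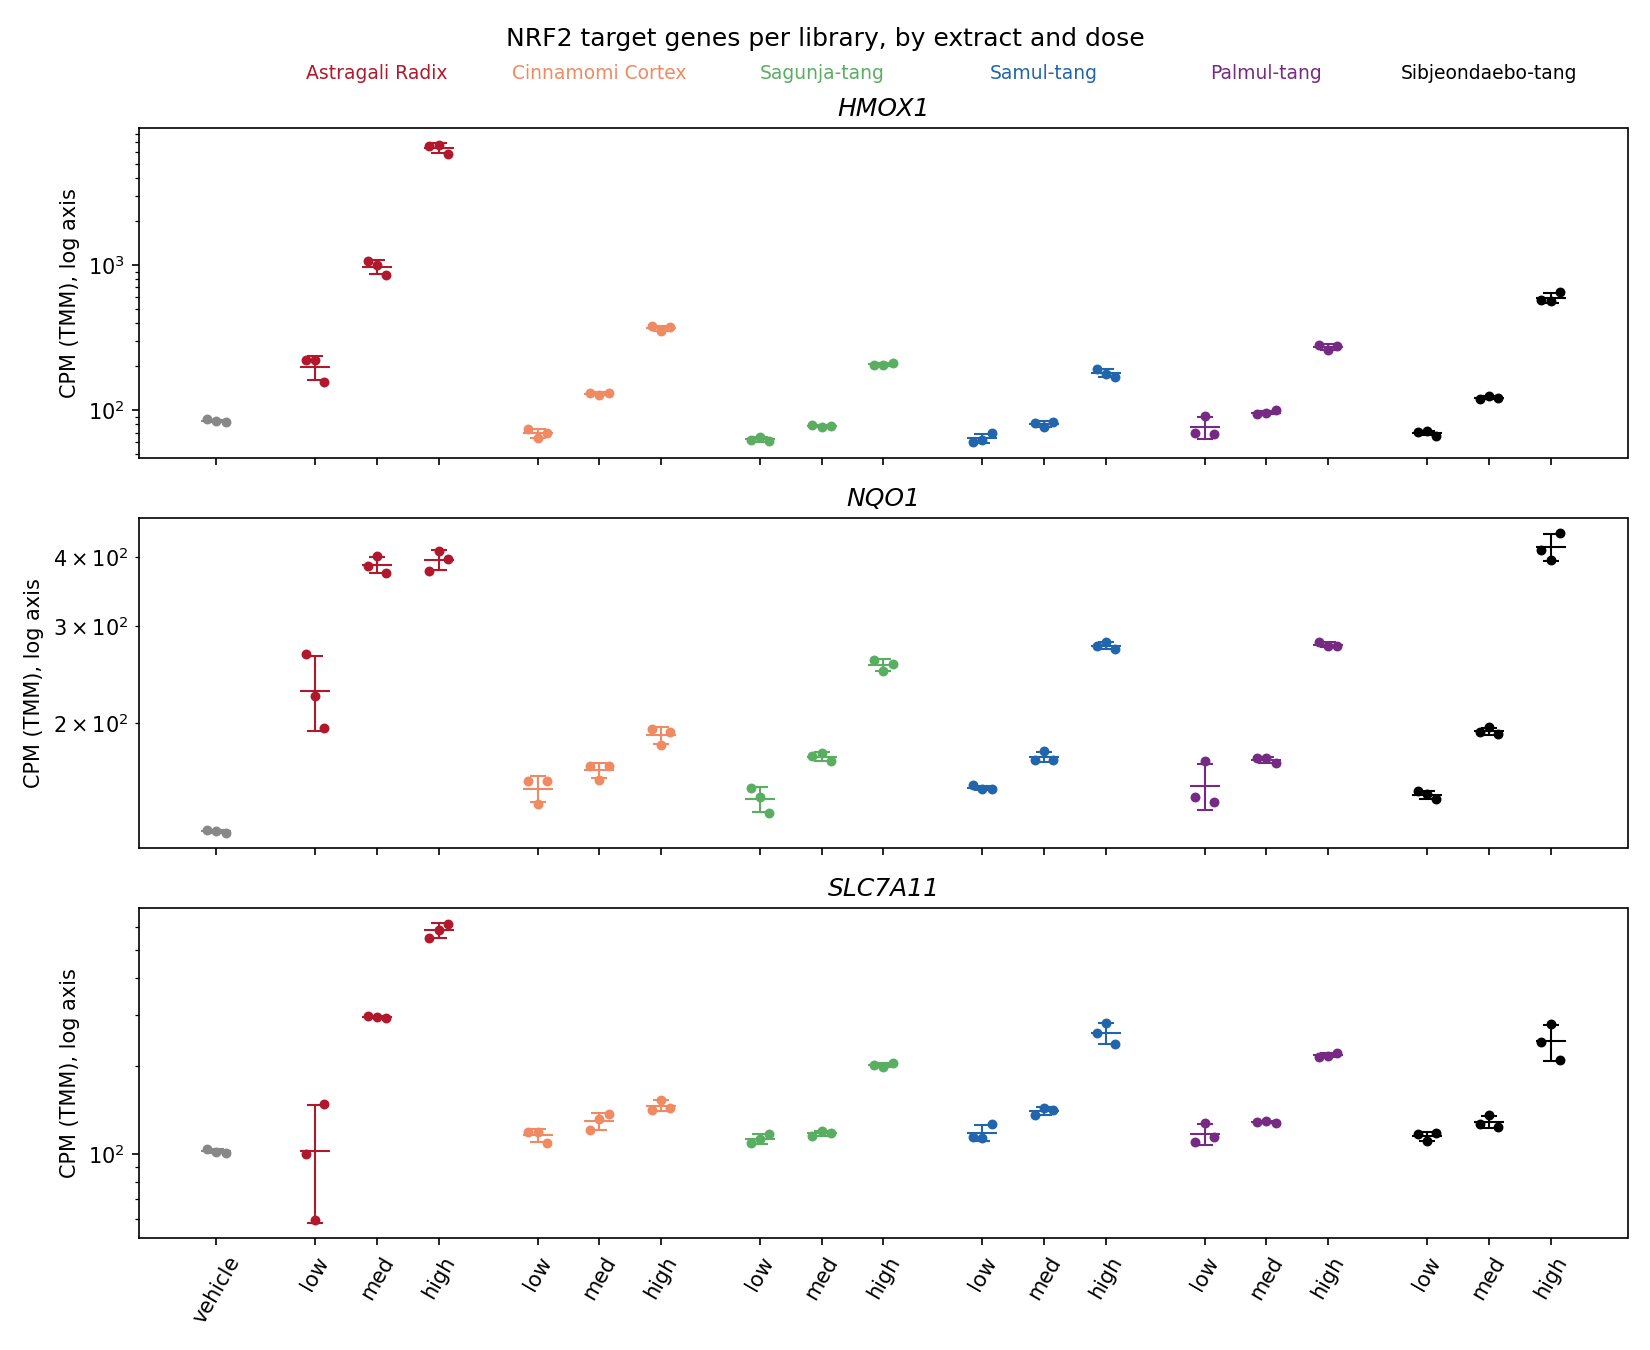
CPM of HMOX1, NQO1 and SLC7A11 (log axes) in each library, for the vehicle and the low, medium and high dose of 6 extracts, with lines at the group means and bars of 1 SD (n = 3). HMOX1 goes from 84.3 CPM in the vehicle to 6371 CPM at the high dose of Astragali Radix and 595 CPM at that of Sibjeondaebo-tang.

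Across extracts, 11 genes rose with dose in all 6 and 2 fell in all 6, where 4.21e-06 and 2.9e-06 would be counted if the calls were independent. These 13 were 7, 8 and 8 without Cinnamomi Cortex high replicate 1, high replicate 3 and low replicate 3, 30 and 25 without Astragali Radix low replicates 2 and 3, and 62 without low replicates 1 and 2 of that herb. HMOX1, NQO1, GCLM, which encodes a subunit of the enzyme that starts glutathione synthesis, and FTH1 were among the 11. In the 4 formulas 50 genes rose and 20 fell in every one, and these 70 were 110, 165 and 120 without Astragali Radix low replicates 1, 2 and 3 and 295 without both replicates 1 and 2. The slopes of Palmul-tang and Sibjeondaebo-tang had a Pearson correlation across genes of 0.265 (0.188 to 0.272 with 1 library left out), or 0.634 over genes of at least 10 CPM. That of Palmul-tang with Sagunja-tang was 0.143 (0.106 to 0.179 with 1 library left out), or 0.627 over genes of at least 10 CPM, and with Samul-tang 0.12, or 0.608. The value of 0.12 was 0.075 without Samul-tang high replicate 1 and 0.058 without Palmul-tang high replicate 3. Pairs with no herb in common by recipe reached similar values over all genes. Astragali Radix with Palmul-tang gave 0.148 and Cinnamomi Cortex with Samul-tang 0.143, or 0.354 and 0.277 over genes of at least 10 CPM. The values over all genes therefore do not set pairs with shared herbs apart. Sagunja-tang with Samul-tang gave 0.238 over genes of at least 10 CPM, while over all genes the sign changed with the library left out, from -0.102 without Sagunja-tang low replicate 1 to 0.045 without low replicate 2 (-0.034 with all libraries, jackknife SE 0.124). These correlations share no library between the extracts, and genes are not independent replicates. Palmul-tang and Sibjeondaebo-tang shared 255 genes called higher and 240 called lower, against 35.9 and 33.4 if independent.

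Palmul-tang and its component formulas were compared at the high dose to ask how far the combination differed from its parts. All were given at the same total concentration, so the herbs of each part make up only a share of Palmul-tang. The other herbs and a lower amount of the part's own herbs cannot be told apart in these comparisons. BMP and SMAD targets were lower in Palmul-tang than in Sagunja-tang in 7 of 10 (8 adjusted over the list alone, median log2 -1.01, adjusted p = 6.59e-76) and than in Samul-tang in 4 of 10 (9 adjusted over the list alone, median -0.51, adjusted p = 2.32e-16). ID3 was lower by log2 -1.69 ± 0.10 and -0.84 ± 0.10 in these comparisons, and by -1.27 ± 0.09 against the mean of both formulas, where 7 of 10 targets were lower (9 adjusted over the list alone, median -0.80, adjusted p = 1.57e-61). ID2 and ATOH8 were log2 -1.20 ± 0.11 and -1.05 ± 0.13 against that mean, and ATP2A3 was 1.14 ± 0.12 above it. Cholesterol synthesis genes were lower in Palmul-tang than in Sagunja-tang in 8 of 24 (17 adjusted over the list alone, median log2 -0.29, adjusted p = 2.4e-37). ATF4 genes were higher than in Samul-tang in 7 of 21 (11 higher and 1 lower adjusted over the list alone, median log2 0.23, adjusted p = 1.92e-14), and GDF15 was higher by log2 1.02 ± 0.12. All these calls held with an estimated correlation.

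Palmul-tang differed from Sagunja-tang in 162 genes, 69 higher and 93 lower. This count was 107 without Sagunja-tang high replicate 2, 106 without Palmul-tang high replicate 1 and 106 without Palmul-tang high replicate 3. From Samul-tang it differed in 299 genes, 162 higher and 137 lower, and in 149, 173 and 155 without Palmul-tang high replicates 1, 2 and 3, and 152 and 160 without Samul-tang high replicates 1 and 2. From the mean of both it differed in 123 genes, 66 higher and 57 lower, and in 61, 68 and 61 without Palmul-tang high replicates 1, 2 and 3. The Palmul-tang libraries carry another label code than those of Sagunja-tang and Samul-tang, so formula and code cannot be told apart in these 3 comparisons. Of 28 comparisons of 2 groups, none had a correlation of deviations over 0.1 between libraries of the same number for all 3 replicate numbers.

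**Figure D2:**
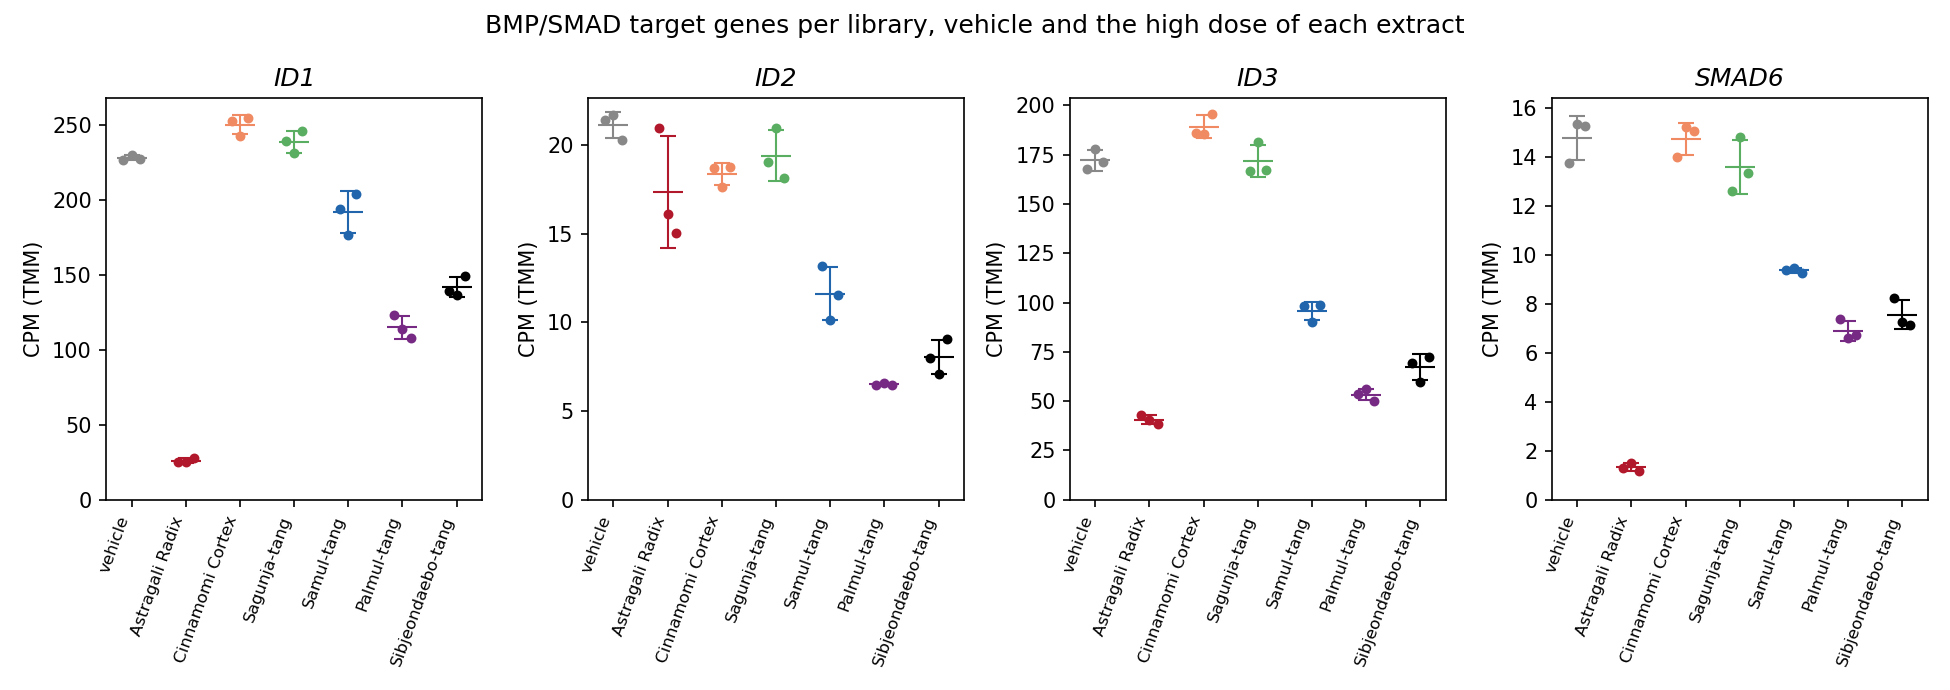
CPM of ID1, ID2, ID3 and SMAD6 in each library, for the vehicle and the high dose of 6 extracts, with lines at the group means, bars of 1 SD (n = 3) and axes from 0. ID3 lies at 172 CPM in the vehicle and at 53.3 CPM in Palmul-tang.

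Sagunja-tang was compared with Samul-tang at the high dose because both are parts of Palmul-tang, and sterol and hypoxia genes differed in opposite directions. Cholesterol synthesis genes were higher in Sagunja-tang in 12 of 24 (17 adjusted over the list alone, median log2 0.34, adjusted p = 7.51e-26), and fatty acid synthesis genes in 6 of 12 (7 adjusted over the list alone, adjusted p = 1.29e-14). BMP and SMAD targets were higher in 6 of 10, also adjusted over the list alone (median log2 0.53, adjusted p = 1.61e-11), with ID3 at log2 0.84 ± 0.10. Hypoxia and glycolysis genes were lower in 12 of 24 with 1 higher (14 and 1 adjusted over the list alone, median log2 -0.25, adjusted p = 1.73e-13). IGFBP1 was lower by log2 -1.07 ± 0.09 and NPTX1, a secreted neuronal pentraxin, by -1.14 ± 0.11. These calls held with an estimated correlation. In all 832 genes differed, 437 higher and 395 lower, and 482, 523 and 544 without Samul-tang high replicates 1, 2 and 3, and 500 and 516 without Sagunja-tang high replicates 2 and 3.

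Sibjeondaebo-tang and Palmul-tang were compared at the high dose to ask what differed once Astragali Radix and Cinnamomi Cortex were part of the formula. Both were given at the same total concentration, so the added herbs and a lower amount of the Palmul-tang herbs cannot be told apart. NRF2 targets were higher in Sibjeondaebo-tang in 17 of 25 (20 adjusted over the list alone, median log2 0.34, adjusted p = 1.36e-32), HMOX1 by log2 1.13 ± 0.09 (adjusted p = 4.2e-12) and NQO1 by 0.59 ± 0.06. ALAS1, the rate-limiting enzyme of heme synthesis, was higher by log2 0.60 ± 0.05. Hypoxia and glycolysis genes were higher in 10 of 24 with 1 lower (16 and 1 adjusted over the list alone, median log2 0.27, adjusted p = 2.4e-09). DHRS3 was lower by log2 -0.90 ± 0.12, and of 6 metallothionein and zinc genes 2 were lower, also adjusted over the list alone (adjusted p = 0.0103). These calls held with an estimated correlation. Ribosomal protein genes were higher in 2 of 32 (3 adjusted over the list alone, median log2 0.18, adjusted p = 4.12e-09; adjusted p = 0.251 with an estimated correlation). Nuclear oxidative phosphorylation genes had a median of log2 0.17 with 0 of 27 called by edgeR (adjusted p = 1.96e-06; adjusted p = 0.225 with an estimated correlation). In all 964 genes differed, 309 higher and 655 lower, so 32.1% were higher, against 46.9% once length and GC trends were removed. The share was 51% in a fit of these groups by themselves, which removes no trend. The excess of lower genes therefore depends on the fit and cannot be laid to length and GC. The count was 530, 477 and 565 without Palmul-tang high replicates 1, 2 and 3, and 509 and 306 without Sibjeondaebo-tang high replicates 1 and 3.

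The low doses of all 6 extracts shared a difference from the vehicle libraries. In every one 204 genes were higher and 389 lower, 593 in all, where 0.00123 and 0.00376 would be counted if the calls were independent. Unchanged groups simulated against a shared vehicle gave at most 0, a value that calls in 6 comparisons make likely in any case. Of the genes called without vehicle replicate 1, 2 or 3, 99.5%, 99.8% and 100% lay on the same side of the library left out. The count was 380 without vehicle replicate 1, 1206 without Astragali Radix low replicate 2 and 1894 without low replicates 1 and 2 of that extract. Of genes chosen for these doses after their values were seen, NEAT1, a nuclear RNA that builds paraspeckles, was higher in the low doses by log2 0.96 to 1.33. CCL2, a chemokine gene, was lower by log2 -1.03 to -0.78, and PTGS2, an inducible enzyme of prostaglandin synthesis, by -0.95 to -0.66. NF-kB and inflammatory genes were lower in the low dose of 5 extracts, from 9 of 21 in Cinnamomi Cortex (11 adjusted over the list alone, median log2 -0.34, adjusted p = 7.12e-09) to 6 of 21 in Sagunja-tang (7 adjusted over the list alone, adjusted p = 0.00101), calls that held with an estimated correlation, but not called in Astragali Radix (adjusted p = 0.221). There the alternatives gave adjusted p = 0.0152 to 0.281, with calls without low replicates 1 and 2 (0.0152, a group of 1 library) and with length and GC trends removed (0.0161). Mitochondrially encoded genes had medians of log2 -1.08 to -0.45 in the low doses, and adjusted p = 0.149 to 0.404 with an estimated correlation. They took 7.55% to 8.04% of the counts in the vehicle libraries and 1.38% to 7.18% in the 57 extract libraries. G2/M and mitosis genes had medians of log2 -0.30 to -0.18 in the low doses, and adjusted p = 0.0547 to 0.204 with an estimated correlation. In the 3 Rehmanniae Radix Preparata libraries the 204 genes had medians of log2 0.44, 0.52 and 0.54 and the 389 genes -0.35, -0.37 and -0.35 at the high, medium and low dose. The genes were chosen with the same vehicle libraries, so a part of these medians may come from the choice. The titles give all 60 libraries 1 batch name, and a label code of unstated meaning follows the extracts. No extract library carries the code of the vehicle libraries, so extract and code cannot be told apart in any comparison with the vehicle. Part of the overlap may come from the shared vehicle libraries, which are too few to split.

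Against the vehicle, the medium and low doses of the other extracts changed these numbers of genes, in which extract and label code cannot be told apart. Cinnamomi Cortex changed 2302 and 2341, the medium count being 1386, 1514 and 1491 without vehicle replicates 1 and 3 and medium replicate 3, and the low count 1439 and 1499 without vehicle replicate 1 and low replicate 3. Sagunja-tang changed 2378 and 2486, the medium count being 1557 and 1579 without vehicle replicate 1 and medium replicate 2, and the low count 1487, 1651 and 1550 without vehicle replicates 1 and 3 and low replicate 2. Samul-tang changed 2131 and 2002, the medium count being 1251, 1363, 1254 and 1415 without vehicle replicates 1 and 3 and medium replicates 2 and 3, and the low count 1233, 1328, 1288 and 1326 without vehicle replicates 1 and 3 and low replicates 1 and 3. Palmul-tang changed 1800 and 1739, the medium count being 1100, 1199, 1145, 1061 and 1134 without vehicle replicates 1, 2 and 3 and medium replicates 1 and 2, and the low count 1006, 1102, 1041 and 1088 without vehicle replicates 1 and 3 and low replicates 2 and 3. Sibjeondaebo-tang changed 1018 and 1698, the medium count being 541, 570, 610, 538 and 605 without vehicle replicates 1 and 3 and medium replicates 1, 2 and 3, and the low count 1032, 1111, 1128, 1103 and 1068 without vehicle replicates 1, 2 and 3 and low replicates 1 and 2.

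**Figure D3:**
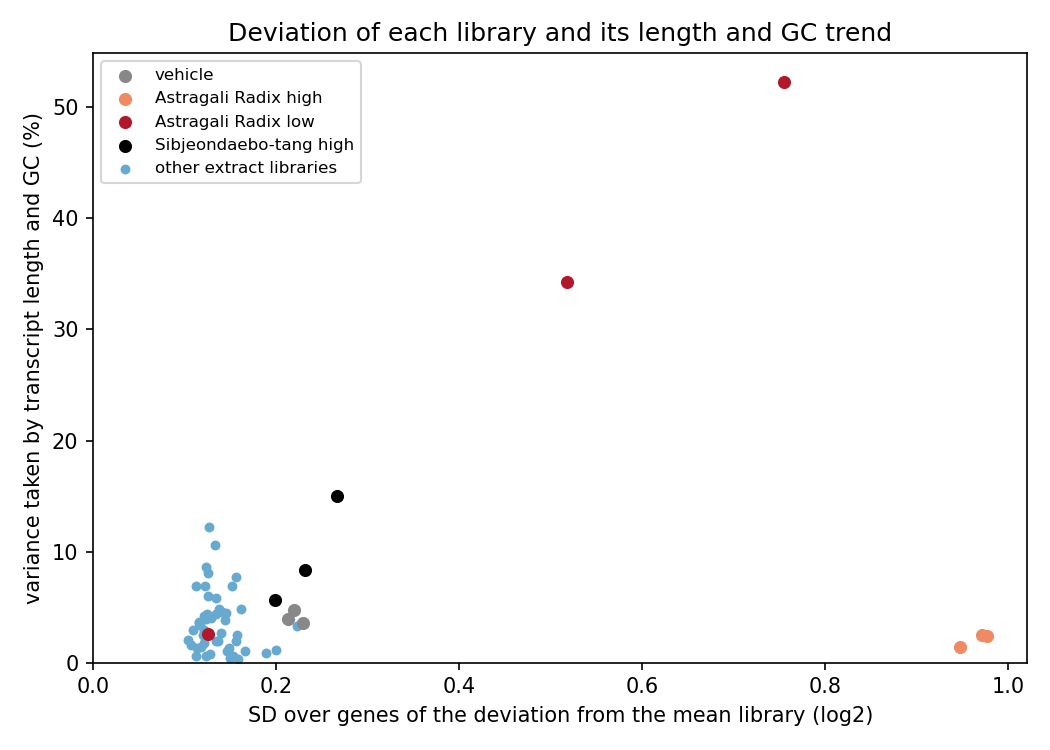
Each point is 1 of the 60 libraries. The x axis is the SD over genes of its log2 deviation from the mean of the replicated libraries outside the high and low dose of Astragali Radix. The y axis is the percentage of that variance taken by transcript length and GC. The points at 34.3% and 52.3% are Astragali Radix low replicates 1 and 2.

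**Figure D4:**
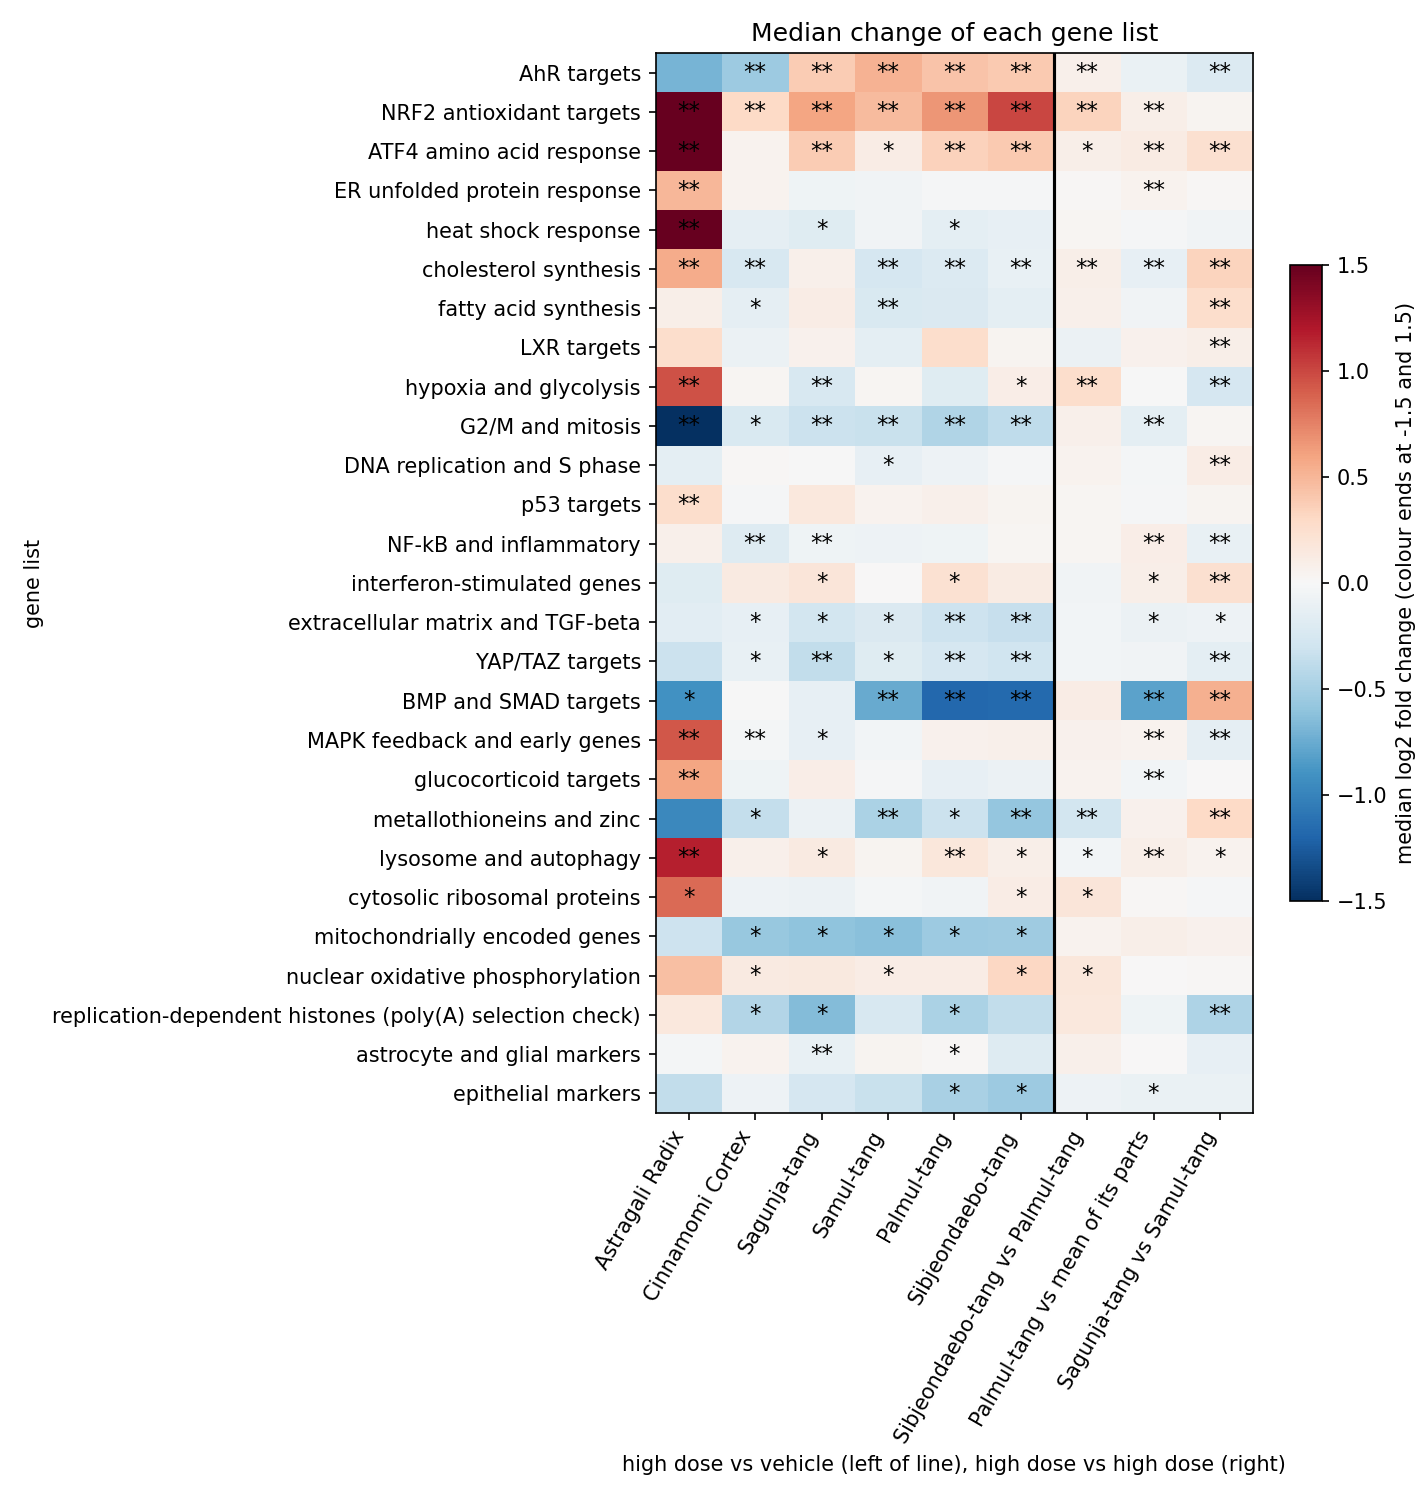
Median log2 change of the members of each gene list (colour, ending at -1.5 and 1.5) at the high dose of each extract against the vehicle and between extracts, for lists called in a comparison drawn; 1 star marks a call with the preset correlation and 2 stars one that also holds with an estimated correlation. NRF2 targets are called in all 6 extracts, with medians from log2 0.30 to 2.23.

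Of the remaining lists, extracellular matrix and TGF-beta genes were called lower against the vehicle at every dose apart from the high and low dose of Astragali Radix, in most cases with the preset correlation alone. The calls that held with an estimated correlation were the high dose of Palmul-tang (12 of 22 fell, 13 adjusted over the list alone, median log2 -0.31, adjusted p = 8.63e-13; adjusted p = 0.0348 with an estimated correlation) and of Sibjeondaebo-tang (16 of 22, 17 adjusted over the list alone, median -0.34, adjusted p = 1.59e-11; adjusted p = 0.0489 with an estimated correlation), and the dose trends of Sagunja-tang (4 of 22, 5 adjusted over the list alone, adjusted p = 2.96e-12; adjusted p = 0.023 with an estimated correlation) and Palmul-tang (5 of 22, 7 adjusted over the list alone, adjusted p = 2.69e-11; adjusted p = 0.0294 with an estimated correlation). The other calls of this list against the vehicle had adjusted p = 0.0537 to 0.48 with an estimated correlation, those of the dose trends of Samul-tang and Sibjeondaebo-tang 0.129 and 0.133, and those between extracts 0.233 to 0.453. Interferon-stimulated genes were higher in Palmul-tang than in Samul-tang in 1 of 22 (4 adjusted over the list alone, adjusted p = 6.05e-08) and in Sagunja-tang than in Samul-tang in 3 of 22 (9 adjusted over the list alone, adjusted p = 1.86e-06), calls that held with an estimated correlation. Their rises at the high dose of Sagunja-tang (6 of 22) and Palmul-tang (7 of 22) had adjusted p = 0.281 and 0.316 with an estimated correlation. Genes of DNA replication and S phase fell in 6 of 24 at the high dose of Samul-tang (7 adjusted over the list alone, adjusted p = 0.0259; adjusted p = 0.309 with an estimated correlation), and with dose of Palmul-tang in 1 of 24, also adjusted over the list alone (adjusted p = 7.62e-06; adjusted p = 0.0195 with an estimated correlation). LXR targets were called in 4 comparisons, with the lowest adjusted p for the fall of 1 of 7 with dose of Samul-tang (3 adjusted over the list alone, adjusted p = 0.000101). Replication-dependent histones, whose transcripts lack a poly(A) tail, fell at the high dose of Cinnamomi Cortex, Sagunja-tang and Palmul-tang in 4, 5 and 3 of 10, with adjusted p = 0.201, 0.0998 and 0.177 with an estimated correlation, and were lower in Sagunja-tang than in Samul-tang in 1 of 10 (3 adjusted over the list alone, adjusted p = 0.00299; adjusted p = 0.0405 with an estimated correlation).

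Among cell type markers, epithelial genes fell in 3 of 5 at the high dose of Palmul-tang and of Sibjeondaebo-tang (adjusted p = 0.00432 and 0.00178, or 0.165 and 0.134 with an estimated correlation). They also fell in 3 of 5 at the medium dose of Astragali Radix (adjusted p = 4.44e-05) and with dose of Palmul-tang (1 higher and 3 lower adjusted over the list alone, adjusted p = 5.13e-05), calls that held with an estimated correlation. Astrocyte and glial markers fell in 3 of 8 at the high dose of Sagunja-tang (adjusted p = 0.0174), also adjusted over the list alone. At the high dose of Palmul-tang the list test called them lower (adjusted p = 0.0394; adjusted p = 0.078 with an estimated correlation) while their median and mean were log2 0.02 and 0.03, and at the medium dose of Sagunja-tang lower (adjusted p = 0.0379; adjusted p = 0.0754 with an estimated correlation) with a median of 0.01 and a mean of -0.01. Leukocyte markers fell in 2 of 6 at the medium dose of Astragali Radix (adjusted p = 0.0239; adjusted p = 0.0552 with an estimated correlation), and neuron markers in 1 of 7 with dose of Palmul-tang (adjusted p = 0.044; adjusted p = 0.0594 with an estimated correlation). Hepatocyte markers and endothelial and mural markers were called in 0 of 29 comparisons by the list test.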

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

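The 4 tests on Astragali Radix low replicates 1 and 2 were chosen after the result was seen, as were the test in vehicle libraries left out and the correlations with 1 library left out for Sibjeondaebo-tang against Palmul-tang, and the other tests of this part before. Direct tests between extracts at the high dose found differences, in which the label code follows the formula where Palmul-tang is set against Sagunja-tang or Samul-tang: 162 genes between Palmul-tang and Sagunja-tang, 299 between Palmul-tang and Samul-tang, 964 between Sibjeondaebo-tang and Palmul-tang, 832 between Sagunja-tang and Samul-tang, and 123 between Palmul-tang and the mean of its parts. Leaving out 1 library gave values of 106 to 117, 149 to 207, 306 to 1129, 482 to 561 and 61 to 109, and those over 1.5 times from the reported value are named with their library among the results. For Palmul-tang against the mean, 2 of 100 splits of the 9 libraries, the real one included, gave at least the real count. In fits of these groups by themselves the real one gave 642 genes and the other 725. The splits also mix Sagunja-tang and Samul-tang libraries, which differ from each other, so this count does not exclude chance.

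The Rehmanniae Radix Preparata libraries, which enter no test and appear among the results for the genes shared by the low doses alone, showed signals beyond the vehicle libraries at the high dose. The median of 8 AhR targets was log2 0.814 above the vehicle mean, with 7 of 8 above all 3 vehicle libraries, and that of 25 NRF2 targets log2 0.155, with 20 of 25 above. Both lie at the 100th percentile of 10000 random lists of matched expression. At the medium dose the medians were log2 -0.053 and -0.009 (percentiles 33.11 and 76.95) and at the low dose 0.138 and 0.076 (percentiles 94.43 and 99.8), so the values do not rise step by step with dose, and a percentile near 100 does not by itself mark a response to the high dose. Against the low dose of the same extract, a comparison in which no vehicle library takes part, the medians were log2 0.731 and 0.215. Each dose is 1 library, so no test was made.

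Astragali Radix low replicates 1 and 2 stand apart from the other libraries. A response to the low dose is argued against by replicate 3, whose deviation had a correlation over genes of -0.031 with the mean of the 2. Reads counted on the wrong strand would raise genes lying opposite an abundant gene by at least log2 1, and these rose by at most 0.198 above genes with no overlap. Transcript length and GC took 34.3% and 52.3% of the variance, more than the 15% of any other library outside the high dose, but less than the 40% set for the lower one, so a trend may account for a part. It leaves an SD over genes of 0.419 and 0.521, against at most 0.246 in libraries outside the high dose of Astragali Radix, and is not the whole cause.

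In all 6 low doses the same 593 genes differ from the vehicle libraries, or 380 to 1206 with 1 library left out. The 20 simulated sets that share a vehicle but no effect gave at most 0 such genes, which decides nothing, and a mean correlation of log2 changes between low doses of at most 0.587 (observed 0.588) with a mean covariance of at most 0.0471 (observed 0.1266). Chance values that differ between the vehicle libraries are argued against by genes chosen without 1 of them. At least 99.5% of these genes lay on the same side of the library left out. A chance state shared by all vehicle libraries would give the same result, so the test cannot decide on it. The labels do not say whether the replicates were separate cultures. Removing length and GC trends left 533 of the genes called the same way, which argues against such a trend. The titles give all libraries 1 batch name, but handling that follows the label code could give the same pattern and cannot be told apart from a biological response shared by all extracts or a difference in DMSO, both untested, since 0 extract libraries carry the code of the vehicle.

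Sibjeondaebo-tang at the high dose differs from Palmul-tang, and ribosomal protein and nuclear oxidative phosphorylation genes are called higher with the preset correlation alone (adjusted p = 0.251 and 0.225 with an estimated one). A length or GC trend is argued against for these lists: removing it left medians of log2 0.174 and 0.182, against 0.181 and 0.17 before, and preset adjusted p of at most 1.35e-05. The difference correlated over all genes at 0.204 with that of Astragali Radix between the high and the medium dose. With 1 library left out this value was 0.146 (without Sibjeondaebo-tang high replicate 3) to 0.202, in most cases below the level of 0.2 set in advance. Over genes of at least 10 CPM, a subset not named when that level was set, the correlation was 0.302 (0.286 to 0.312). Whether a response to this herb adds to that of Palmul-tang stays open. The same difference correlated at 0.034 (-0.016 to 0.067 with 1 library left out), and at -0.002 over genes of at least 10 CPM, with the difference of Cinnamomi Cortex between the high and the low dose. These values lie below the level of 0.2. The dose test of that herb called 78 of 17676 genes, too few for a correlation over all genes to decide whether it adds a part. These are correlations across genes, which are not independent replicates, and library handling stays open.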

How the results depend on the processing

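The removal of length and GC trends and the fits without Astragali Radix low replicates 1 and 2 were chosen after the data were seen, and the other alternatives before. With RLE size factors in place of TMM and with no filter beyond 1 count, all 29 counts of called genes stayed within 1.5 times the reported ones, and so they did with replicate as a block in the fit. DESeq2 gave 1 count outside that range, 122 for Cinnamomi Cortex with dose. Of 899 tests of gene lists 356 gave a call, and 206 with an estimated correlation. RLE size factors lost 1 call and gained 1, the block lost 2 and gained 5, the removal of length and GC trends lost 13 and gained 32, and the fit without the 2 libraries lost 18, gained 36 and turned 1. Depth was not varied, and at the depth of these libraries 19 of 50 genes given the smallest change in the self-test were recovered.

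With length and GC trends removed, the counts were at the high dose against the vehicle 4555 for Cinnamomi Cortex. They were at the medium dose against the vehicle 4446 for Astragali Radix, 3606 for Cinnamomi Cortex, 3788 for Sagunja-tang, 3455 for Samul-tang, 3226 for Palmul-tang and 2316 for Sibjeondaebo-tang. They were at the low dose against the vehicle 3778 for Cinnamomi Cortex, 3751 for Sagunja-tang, 3401 for Samul-tang, 3067 for Palmul-tang and 2960 for Sibjeondaebo-tang. They were with dose 226 for Cinnamomi Cortex, 1355 for Sagunja-tang, 586 for Samul-tang and 1387 for Palmul-tang. They were between extracts 411 for Palmul-tang against Sagunja-tang, 699 for Palmul-tang against Samul-tang, 2177 for Sibjeondaebo-tang against Palmul-tang, 1707 for Sagunja-tang against Samul-tang and 289 for Palmul-tang against the mean of its parts. The common dispersion was 0.00656 as reported, 0.00326 with the trends removed and 0.00153 without Astragali Radix low replicates 1 and 2, with a lower median SE in all 29 comparisons of both fits, and in 27 of 29 in fits of the compared groups by themselves. The cause of the higher counts was not tested further. Of the genes that differed between Sibjeondaebo-tang and Palmul-tang, 32.1% were higher as reported, 46.9% with the trends removed, 51% in the fit of these groups by themselves and 52.8% without the 2 libraries.

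In fits of the compared groups by themselves, the counts were at the high dose against the vehicle 6375 for Cinnamomi Cortex, 7222 for Sagunja-tang, 6605 for Samul-tang and 6895 for Palmul-tang. They were at the medium dose against the vehicle 6227 for Astragali Radix, 5599 for Cinnamomi Cortex, 5570 for Sagunja-tang, 5026 for Samul-tang, 4905 for Palmul-tang and 3752 for Sibjeondaebo-tang. They were at the low dose against the vehicle 5044 for Cinnamomi Cortex, 5903 for Sagunja-tang, 5170 for Samul-tang, 5012 for Palmul-tang and 4836 for Sibjeondaebo-tang. They were with dose 414 for Cinnamomi Cortex, 2278 for Sagunja-tang, 818 for Samul-tang, 2304 for Palmul-tang and 6284 for Sibjeondaebo-tang. They were between extracts 783 for Palmul-tang against Sagunja-tang, 1537 for Palmul-tang against Samul-tang, 3127 for Sibjeondaebo-tang against Palmul-tang, 2722 for Sagunja-tang against Samul-tang and 642 for Palmul-tang against the mean of its parts. The low dose of Astragali Radix gave 0 by edgeR in that fit and 7139 by DESeq2 over all groups.

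Without Astragali Radix low replicates 1 and 2, where the 1 library left in the group is assumed to vary like the others, the counts were at the high dose against the vehicle 6027 for Cinnamomi Cortex, 7192 for Sagunja-tang, 6545 for Samul-tang, 6671 for Palmul-tang and 7041 for Sibjeondaebo-tang. They were at the medium dose against the vehicle 6206 for Astragali Radix, 5469 for Cinnamomi Cortex, 5650 for Sagunja-tang, 5284 for Samul-tang, 4829 for Palmul-tang and 3701 for Sibjeondaebo-tang. They were at the low dose against the vehicle 5423 for Cinnamomi Cortex, 5703 for Sagunja-tang, 5108 for Samul-tang, 4745 for Palmul-tang and 4727 for Sibjeondaebo-tang. They were with dose 531 for Cinnamomi Cortex, 2392 for Sagunja-tang, 1103 for Samul-tang, 2171 for Palmul-tang and 7109 for Sibjeondaebo-tang. They were between extracts 806 for Palmul-tang against Sagunja-tang, 1535 for Palmul-tang against Samul-tang, 4290 for Sibjeondaebo-tang against Palmul-tang, 2864 for Sagunja-tang against Samul-tang and 610 for Palmul-tang against the mean of its parts. The low dose of Astragali Radix gave 2920, of which 1418 were among the 7201 reported and called in the same direction. Directions turned for that comparison in COL1A1 (log2 -0.147), TPI1 (-0.026), TOP2A (0.025) and DDIT3 (-0.068), and the list of cytosolic ribosomal proteins turned with an adjusted p of 0.386, against 4.57e-10 as reported and 0.281 with an estimated correlation. The cause was not tested.

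Each library was also left out in turn, and a group of 2 was then assumed to vary like the others. At the high dose against the vehicle the counts lay at 11285 to 11618 for Astragali Radix, 1878 to 2134 for Cinnamomi Cortex, 2962 to 3301 for Sagunja-tang, 2294 to 2948 for Samul-tang, 2614 to 2874 for Palmul-tang and 2830 to 3485 for Sibjeondaebo-tang. At the medium dose against the vehicle the counts lay at 2024 to 2369 for Astragali Radix, 1386 to 1682 for Cinnamomi Cortex, 1557 to 1863 for Sagunja-tang, 1251 to 1590 for Samul-tang, 1061 to 1293 for Palmul-tang and 538 to 693 for Sibjeondaebo-tang. At the low dose against the vehicle the counts lay at 5838 to 9656 for Astragali Radix, 1439 to 1853 for Cinnamomi Cortex, 1487 to 1780 for Sagunja-tang, 1233 to 1428 for Samul-tang, 1006 to 1242 for Palmul-tang and 1032 to 1139 for Sibjeondaebo-tang. With dose they lay at 11745 to 12678 for Astragali Radix, 43 to 56 for Cinnamomi Cortex, 402 to 458 for Sagunja-tang, 157 to 183 for Samul-tang, 387 to 568 for Palmul-tang and 2201 to 3626 for Sibjeondaebo-tang. Between extracts they lay at 106 to 117 for Palmul-tang against Sagunja-tang, 149 to 207 for Palmul-tang against Samul-tang, 306 to 1129 for Sibjeondaebo-tang against Palmul-tang, 482 to 561 for Sagunja-tang against Samul-tang and 61 to 109 for Palmul-tang against the mean of its parts. COL1A1 at the low dose of Astragali Radix against the vehicle lay at log2 -0.181 to 1.062, the lowest without low replicate 2.

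Correlations of dose slopes over genes of at least 10 CPM were 0.118 for Astragali Radix and Cinnamomi Cortex, 0.165 for Astragali Radix and Sagunja-tang, 0.307 for Astragali Radix and Samul-tang, 0.354 for Astragali Radix and Palmul-tang, 0.345 for Astragali Radix and Sibjeondaebo-tang, 0.24 for Cinnamomi Cortex and Sagunja-tang, 0.277 for Cinnamomi Cortex and Samul-tang, 0.341 for Cinnamomi Cortex and Palmul-tang, 0.203 for Cinnamomi Cortex and Sibjeondaebo-tang, 0.238 for Sagunja-tang and Samul-tang, 0.627 for Sagunja-tang and Palmul-tang, 0.367 for Sagunja-tang and Sibjeondaebo-tang, 0.608 for Samul-tang and Palmul-tang, 0.463 for Samul-tang and Sibjeondaebo-tang and 0.634 for Palmul-tang and Sibjeondaebo-tang. With 1 library left out, Cinnamomi Cortex and Sibjeondaebo-tang gave 0.098 (without Cinnamomi Cortex low replicate 1) to 0.268, and the next largest relative fall was to 0.081, for Astragali Radix and Cinnamomi Cortex without Cinnamomi Cortex low replicate 2. Over all genes they lay at -0.04 to 0.265. Without the 2 libraries Astragali Radix and Samul-tang gave 0.071. Under RLE size factors 10 of 93 medians of gene lists in Rehmanniae Radix Preparata moved by more than the spread of the vehicle libraries.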

Other observations

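No test of this part was chosen after its result was seen. The high dose of Rehmanniae Radix Preparata, 1 library, had lower sterol, hypoxia and matrix genes than the vehicle. The 24 cholesterol synthesis genes had a median log2 ratio of -0.19 to the vehicle mean, with 18 below all 3 vehicle libraries and a percentile of 0.04 among random lists. The 24 hypoxia and glycolysis genes had a median of log2 -0.245 (percentile 0.01) and the 22 extracellular matrix and TGF-beta genes -0.252 (percentile 0.02). Nuclear oxidative phosphorylation genes had a median of log2 0.159. Against the low dose of the same extract these 4 medians were log2 -0.187, -0.149, -0.125 and 0.064, so a part of the hypoxia, matrix and oxidative phosphorylation values is shared with the low dose. The 13 mitochondrially encoded genes had a median of log2 -0.377 to the vehicle mean (13 below all 3 vehicle libraries, percentile 0.01), the 25 G2/M and mitosis genes -0.256 (23 below, percentile 0) and the 6 metallothionein and zinc genes -0.418 (4 below, percentile 0.11). Against the low dose these 3 were log2 0.152, -0.06 and -0.147, so the first 2 are mostly shared with the low dose, where they were -0.545 and -0.224. CYP1B1 lay at 241 CPM against 123 CPM in the vehicle.

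The medium dose of Palmul-tang lowered BMP and SMAD targets in 6 of 10 (median log2 -0.37, adjusted p = 0.00034). At the medium dose of Sibjeondaebo-tang NRF2 targets rose in 14 of 25 (16 adjusted over the list alone, median log2 0.31, adjusted p = 3.31e-16) and AhR targets in 2 of 8 (3 adjusted over the list alone, adjusted p = 0.0034). Samul-tang at the medium dose raised AhR targets in 4 of 8 (adjusted p = 0.00744). These calls held with an estimated correlation.

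For the 6 dose trends, 1 of 100 splits of the 9 libraries of each extract, the real one itself, gave as many genes. This argues against chance but does not exclude it, since not all possible splits were drawn. In fits of these groups by themselves the real split gave 8376 genes for Astragali Radix, 414 for Cinnamomi Cortex, 2278 for Sagunja-tang, 818 for Samul-tang, 2304 for Palmul-tang and 6284 for Sibjeondaebo-tang, and the highest other split 6745, 244, 1208, 479, 2264 and 3080. For the 18 comparisons with the vehicle and the 4 comparisons of 2 extracts, the 10 splits of 6 libraries are too few. In 21 of these 22, 1 of 10 splits, the real one, gave as many genes, from 783 to 12191, and the highest other gave 0 to 2. For the low dose of Astragali Radix the real split gave 0 genes, as did the highest other, so all 10 gave as many.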
